A study of Mus musculus with 4 samples.

How the data were processed

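Total RNA from 4 mouse cell cultures was measured on 1 array each. Per the labels, the RNA was treated with DNase, isolated with a column kit and labelled with biotin, and the arrays fall into 4 groups of 1. Both day 6 cultures are bulk cultures of reprogrammable mouse embryonic fibroblasts (fibroblasts that switch on reprogramming factors when doxycycline is added) sampled at day 6 of doxycycline, 1 with a knockdown of Firefly and 1 with a knockdown of Sumo2. Firefly luciferase is an insect gene that mouse cells lack, so that culture was taken as the control. The 2 other arrays hold induced pluripotent stem cells (iPSC), lines derived after Sumo2 knockdown and labelled 38 h and 10 day; the labels do not say what that time counts. The strain is Black6-129X1/SvJ and the sex a pool of male and female, per the labels. The labels carry no replicate numbers, batch or date.

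The deposited values are log2 expression, 1 value per probe set and array, which the authors made with RMA (background correction, quantile normalization and summary over probes) in Affymetrix Expression Console, per the submitters' processing notes; those notes as used here give no versions or settings. The log base is not written in the table. The values run from 2.98 to 13.7 on the 4 arrays, and base 2 was taken because that is the scale RMA writes. Quantile normalization gives arrays nearly equal overall distributions, so a change of total RNA per cell cannot be seen, and RMA pulls fold differences of dim and very bright probe sets towards 0. The array medians over all probe sets were 6.10, 6.10, 6.14 and 6.13 for the Firefly, Sumo2, 38 h and 10 day arrays. Upper quartiles were 7.93, 7.92, 8.14 and 8.17 in that order, so above the median the iPSC arrays stood higher. Arrays give no counting depth, and with 1 array per group their number limits the precision.

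Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none listed; these last are unnamed here, not without a gene. Entrez identifiers of 23328 of the single-symbol probe sets were found in a mouse gene table of assembly GRCm38.p6, which changed 0 symbols and gave each gene's chromosome. Array coordinates were not used because the build of the array design is not given in the sources used here. The single-symbol probe sets stood for 22180 genes, 1082 of them with more than 1 probe set, and the probe set with the highest mean over the 4 arrays was taken. A gene counted as measured in a comparison when it was at or above the median of the single-symbol probe sets on at least 1 of the arrays compared. That median is the measuring floor, 6.64 to 6.67 on the 4 arrays, and a fold counted from it takes values below the floor as equal to it.

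The groups, comparisons, main tests, 27 gene lists and alternatives were chosen before the data were examined. The 2 further lists, several tests of explanations, the differences counted from the floor and the random intervals drawn with scaled values came after results had been seen. With 1 array per group, the comparison of the day 6 cultures and that of the iPSC lines used a size rule of 2-fold and no p-value. The comparison of both iPSC with both day 6 arrays used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2 residual degrees of freedom), with a Benjamini-Hochberg adjusted p under 0.05 and 2-fold as the threshold. The spread in that test includes the knockdown and the difference between the lines, so the arrays of a pair are not replicates of 1 condition, and nothing in the labels says how separate the cultures were. A further comparison took the genes at least 4-fold apart between the mean of both iPSC and the mean of both day 6 arrays and gave the median of their difference between the day 6 cultures. These contrasts are orthogonal, so array noise of equal size gives them no covariance.

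Genes were grouped by 27 fixed lists with 430 genes, 388 of them named by a probe set of their own. A list's median difference was set against 10000 random lists of the same size, matched on mean expression in 20 bins; the random interval below is their central 95%, and it describes these arrays only. Lists with fewer than 3 measured genes got no median. Under the naming rule, the text names Sumo2 first, then the 15 highest and 15 lowest genes that differed at least 2-fold between the day 6 cultures. It then names the 12 highest and 12 lowest genes past the limma threshold that were also 2-fold apart in all 4 pairs of iPSC and day 6 arrays, the 10 highest and 10 lowest between the iPSC lines, up to 4 members of each list with the largest differences, and the reprogramming factors, Nanog, Cdh1, Thy1, Meg3 and Xist. Probe sets with several genes, predicted genes, clone-named genes, olfactory and vomeronasal receptors and small RNA genes, other small non-coding RNAs among them, were left out of the naming. Members that make up a small count within a list are named as well, and these, like any gene that the text says so of, were chosen after their values were seen.

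The alternatives were centring each array on its median, cyclic loess across the arrays, no filter, a filter at the 75th percentile, the median over a gene's probe sets, a 1.5-fold rule, limma with the spread of the iPSC pair alone, eBayes without a trend, leaving out each array in turn, and genes 2-fold instead of 4-fold apart. The scripts were tested on simulated data. With 200 of 12735 genes changed in a simulated comparison of iPSC and day 6 arrays, limma recovered 63% of those changed by 1.5 on the log2 scale and 85% of those changed by 3, with 2 false calls. For the genes 4-fold apart, 20 simulated data sets with no knockdown effect gave medians from -0.06 to 0.03. Of 100 lists of 20 genes drawn at random, 6 fell outside the central 95%. This checks the code, not how often lists of related genes leave the interval between any cultures. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.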

Results

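The data are log2 RMA expression values from 4 arrays, 1 for each of a day 6 culture with Firefly knockdown, a day 6 culture with Sumo2 knockdown, a 38 h iPSC line and a 10 day iPSC line. There are no replicates of any condition. Over all probe sets the day 6 arrays correlated at r = 0.987 and the iPSC arrays at r = 0.985, while each pair of a day 6 and an iPSC array correlated at 0.914 to 0.934; these are correlations across probe sets, which are not independent. The series title places Sumo2, a small ubiquitin-like modifier that is attached to other proteins, among roadblocks to reprogramming found in a screen.

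Sumo2 itself differed little between the day 6 cultures. Its log2 expression was 10.65 with Firefly knockdown and 10.56 with Sumo2 knockdown, so the second culture held 93.8% of the control level. The iPSC lines stood higher, at 11.40 for 38 h and 11.07 for 10 day, and Sumo2 rose 1.55-fold from day 6 cultures to iPSC by adjusted p though not by 2-fold (log2 difference 0.63, SE 0.15, limma adjusted p = 0.0151). The 4 dimmer probe sets that the annotation assigns to Sumo2 together with other genes lay at 79.4% to 84.0% of the control in the Sumo2 knockdown culture. Some of them gave the same values on every array, so they are not all separate readings. Because the transcript does not show the knockdown that the label names, that sample is called the culture labelled Sumo2 knockdown here, and every direction drawn from it rests on its label.

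The first comparison asked what set the culture labelled Sumo2 knockdown apart from the Firefly control at day 6. Genes of the pluripotency network and of epithelial cells were higher in it, and fibroblast genes were lower by smaller steps. Tdgf1, a Nodal co-receptor of pluripotent cells, was at least 4.84-fold higher counted from the measuring floor (log2 5.84 against 8.92), the pluripotency gene Utf1 6.56-fold, the epithelial adhesion gene Epcam 6.40-fold, the core pluripotency factor Nanog 5.02-fold (7.54 against 9.87) and Cdh1, which encodes E-cadherin, 4.52-fold. A second view of Cdh1, the median over its probe sets, put its log2 difference at 1.44 in place of 2.18. Of 11740 measured genes, 111 were at least 2-fold higher and 27 at least 2-fold lower, so 80.4% of these were higher. A 1.5-fold rule gave 480 higher and 330 lower (59.3% higher), so the surplus of higher genes is much smaller among small differences.

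The other genes among the 15 highest were Cyp2b23 (at least 1.83-fold), Prob1 (5.34-fold), the carbonic anhydrase gene Car2 (at least 4.38-fold), Bex1 (4.97-fold), the nuclear receptor gene Nr0b1 (4.96-fold), Ly6g6c (4.79-fold), the epithelial transcription factor gene Grhl3 (at least 3.78-fold), the paternally expressed imprinted gene Peg3 (4.60-fold), Dppa2 (at least 2.64-fold) and Foxh1 (at least 2.19-fold), which encodes a transcription factor of Nodal signalling. Differences in the other direction were smaller. Il1rn, an antagonist of the interleukin 1 receptor, was 3.09-fold lower, Zfp600 at least 1.24-fold and the matrix gene Aspn at least 1.41-fold. Below them came Clec2d (at least 2.43-fold lower), Itgbl1 (2.54-fold), the lymphangiogenic growth factor gene Vegfd (2.46-fold), Tril (2.44-fold), Prok2 (at least 2.19-fold), Ccdc74a (2.43-fold), Vit (at least 1.63-fold), Lvrn (2.36-fold), Aox3 (2.35-fold), S1pr3 (2.32-fold), the complement inhibitor gene Serping1 (2.24-fold) and Npy2r (at least 1.16-fold). Of the 15 named genes on each side, 6 higher and 6 lower ones lay below the measuring floor on the dimmer array. Their folds, marked at least, are counted from the floor, and their ranks, taken from the values as read, rest on background. Cyp2b23, Zfp600, Aspn, Vit and Npy2r did not reach 2-fold counted from the floor.

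In what follows on the lists, differences marked floor are log2 differences counted from the measuring floor, because a value lay below it. Their ranks as read rest on background. Among the fixed lists, 18 of 20 measured pluripotency genes were higher in the culture labelled Sumo2 knockdown, 8 of them at least 2-fold, and Klf2 (-0.50) and Lefty1 (floor -0.16) were lower. Their median log2 difference was 0.80, against a random interval of -0.13 to 0.18, with Tdgf1, Utf1, Nanog and Nr0b1 leading. Of 16 epithelial genes, 15 were higher, all but Krt18 (-0.15), and 8 at least 2-fold so (7 counted from the floor), with a median of 1.06 (random interval -0.15 to 0.20) and the membrane protease gene St14 (1.73) and the desmosome gene Dsp (floor 1.59) next after Epcam and Cdh1. All 25 measured fibroblast and mesenchymal genes were lower, with a median of -0.48 (random interval -0.09 to 0.13), but 0 reached 2-fold. Some of them, such as Fn1 (-0.002), Vim (-0.03) and Prrx1 (-0.09), were nearly equal in both cultures. The matrix proteoglycan gene Dcn (-0.88), the matrix protease gene Mmp2 (-0.77) and the collagen gene Col5a1 (-0.73) differed most among those above the floor in both. The fibroblast surface marker Thy1 went from 11.71 to 11.23. Of 15 TGF-beta target and contractile genes 14 were lower, all but Ltbp1 (0.42) (median -0.30, random interval -0.13 to 0.16), 1 of them at least 2-fold: Tgfbi, at -1.03.

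**Figure D1:**
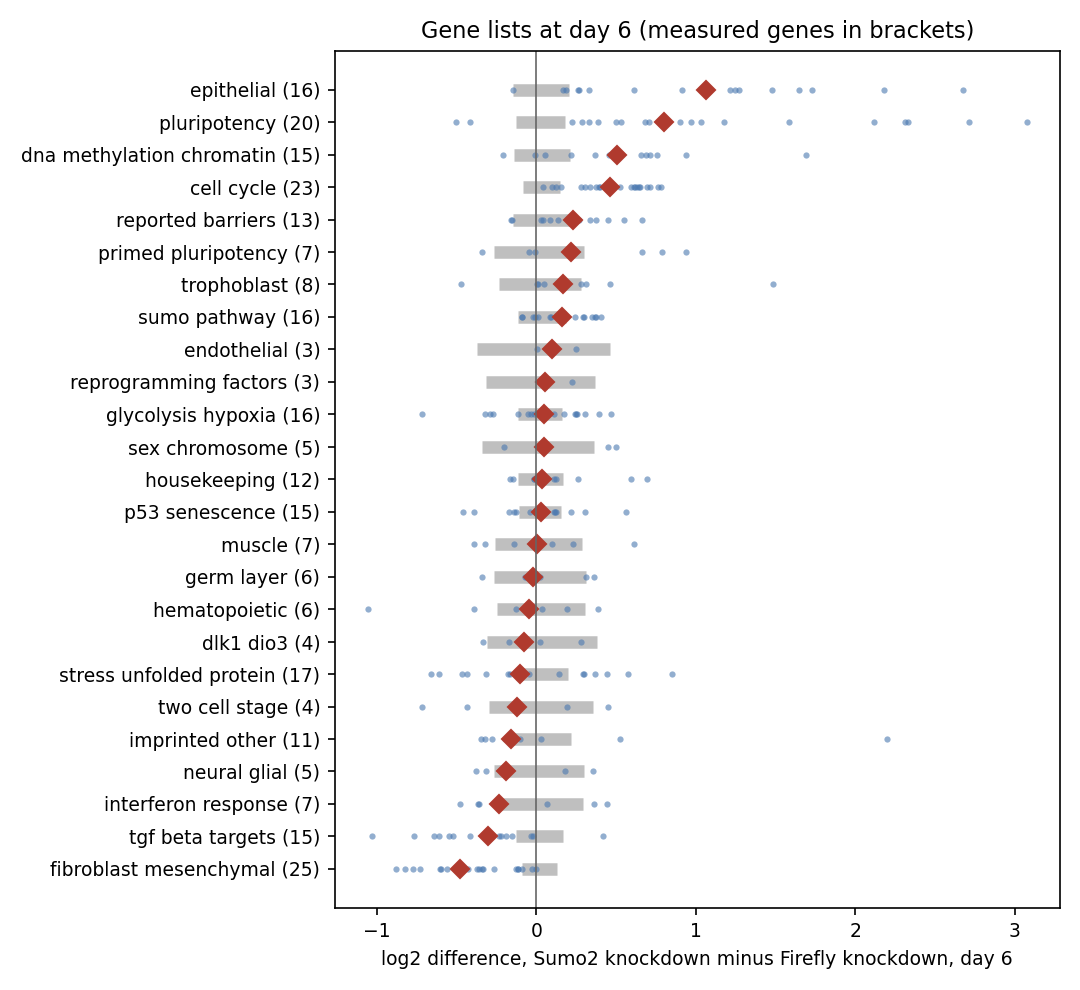
Log2 difference between the day 6 culture labelled Sumo2 knockdown and the Firefly control (x axis) for each fixed gene list with at least 3 measured genes (y axis, number measured in brackets); dots are genes, diamonds list medians and grey bars the central 95% of medians of 10000 random lists. The epithelial (1.06) and pluripotency (0.80) medians lay highest and the fibroblast median (-0.48) lowest.

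Proliferation genes were also higher. Each of the 23 measured cell cycle genes was higher (22 of 23 after cyclic loess), 0 by 2-fold, with a median of 0.46 (random interval -0.08 to 0.15) and the mitotic checkpoint kinase gene Bub1b (0.78) and the replication helicase gene Mcm3 (0.76) first. Of 15 DNA methylation and chromatin genes 13 were higher, all but Kdm4c (-0.21) and Tet3 (-0.01) (median 0.50, random interval -0.14 to 0.21). The 5-methylcytosine oxidase gene Tet1 was higher by 1.69, the de novo methyltransferase gene Dnmt3b by 0.94, and Uhrf1 (0.76) and Dnmt1 (0.71), which maintain methylation, by less. The list of genes reported to hinder reprogramming was fixed beforehand, and whether each member, such as Kdm6a, does so was not checked. Genes on it were higher in 11 of 13 cases, all but Nr2c1 (-0.16) and Tgfbr1 (-0.15) (median 0.23, random interval -0.15 to 0.22), led by the chromatin assembly genes Chaf1a (0.66) and Chaf1b (0.55). That median stood only just above the interval. After cyclic loess, which left 9 of 13 genes higher, it was 0.15, again only just above an interval of -0.21 to 0.15 drawn with the scaled values.

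The reprogramming factors differed little. Pou5f1 was at 7.56 and 7.58, Klf4 at 11.93 and 12.15, and Myc at 9.37 and 9.43 in control and in the culture labelled Sumo2 knockdown, while Sox2 lay below the measuring floor in both day 6 cultures (6.10 and 6.55). Probe sets can read a transgene and the endogenous gene alike where both carry their target sequence. For Pou5f1, Klf4 and Myc these arrays do not tell which was read. The Sox2 probe set read little of either at day 6, though both cultures had doxycycline. Pou5f1 read only 8.56 and 8.39 in the 38 h and 10 day lines, where Nanog read 12.05 and 12.50. How well the Pou5f1 probe set responds was not tested, so its small differences carry little weight. SUMO pathway genes had a median of 0.16, inside the random interval of -0.12 to 0.18, with 0 of 16 differing 2-fold.

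The medians of the other lists lay inside their random intervals with the deposited values, close to the edge for a few, and they cover other cell types that the culture could hold. Median log2 differences were -0.05 for 6 blood and macrophage markers, 0.10 for 3 endothelial, -0.19 for 5 neural and glial, and 0.00 for 7 muscle markers. Counted from the floor, 0 members of these reached 2-fold, the macrophage gene Lyz2 (floor -0.47) included. Of the keratinocyte list only Sfn (-0.20) and Sprr1a (0.02) were measured, and of the adipocyte list 0 genes. The medians were 0.16 for 8 trophoblast genes, with Tfap2c higher (floor 1.39), 0.22 for 7 primed pluripotency genes, -0.02 for 6 germ layer genes, and -0.12 for 4 genes of the 2-cell stage. Further medians were 0.03 for 15 p53 and senescence genes, -0.23 for 7 interferon response genes (random interval -0.24 to 0.29, and -0.26 after cyclic loess, just below an interval of -0.26 to 0.26 drawn with the scaled values), -0.10 for 17 stress genes (random interval -0.13 to 0.20), 0.05 for 16 glycolysis and hypoxia genes and 0.03 for 12 widely expressed genes. Of 11 imprinted genes outside the Dlk1-Dio3 cluster the median was -0.16 (random interval -0.16 to 0.22) but the mean 0.09, with Peg3 2.20 higher, so the list gives no direction, and 4 genes of that cluster had a median of -0.08, with Meg3 at 6.66 and 6.68. The 5 sex chromosome genes had a median of 0.04, and Xist, the RNA that silences an X chromosome, was at 6.22 and 6.72.

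These day 6 differences compare 1 array with 1 and have no replicate check. Of 25 list medians, 5 lay above and 2 below their random intervals, against 1.25 expected by chance. Between the iPSC lines 4 lay above and 4 below of 26, against 1.30 expected. A list median outside its interval is therefore not particular to the culture labelled Sumo2 knockdown. The log2 differences of the day 6 pair had an SD of 0.33 over genes, less than the 0.41 of the iPSC pair. With the spread of the iPSC pair as the error (1 residual degree of freedom), limma called 0 genes at adjusted p under 0.05, and 722 of 11740 genes (6.15%) at an unadjusted p under 0.05.

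The second comparison asked how the iPSC lines differed from the day 6 cultures. Pluripotency genes, glycolysis genes and genes of the 2-cell stage rose, and p53 target genes and many fibroblast genes fell. Sox2 lay below the measuring floor in both day 6 cultures and rose at least 40.3-fold counted from that floor (log2 difference as read 5.67, SE 0.20, limma adjusted p = 0.000105, higher in both lines than in both day 6 cultures), and Tdgf1 at least 31.3-fold (5.37 as read, SE 0.87, limma adjusted p = 0.0042) with day 6 values of 5.84 and 8.92. The BMP antagonist gene Sostdc1 fell most as read, at least 27.7-fold counted from the floor, below which it lay in both lines (log2 difference -5.64, SE 0.25, limma adjusted p = 0.000105) and the surface marker gene Cd34 fell 28.9-fold (-4.85, SE 0.17, limma adjusted p = 0.000105). In all, 1820 of 12735 measured genes rose and 1161 fell at least 2-fold at adjusted p under 0.05 (61.1% of them up). Cyclic loess gave 1479 up and 1383 down (51.7%), so the surplus of rising genes depends on scaling. With the deposited values 1921 of the measured genes passed these criteria and were 2-fold apart one way in all 4 pairs of arrays.

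Of the 12 genes named on each side here, 10 that rose lay below the measuring floor in both day 6 cultures and 9 that fell lay below it in both lines, while Tdgf1, Pla2g1b and Ano1 lay below it on 1 array. For these, folds marked at least are counted from the floor, and their order as read, which is kept here, rests on background. The other genes that rose most were Zscan4e (at least 19.3-fold), Zfp981 (at least 38.9-fold), the potassium channel gene Kcnma1 (at least 53.6-fold), Zscan4b (at least 15.4-fold), Zfp640 (at least 14.7-fold), the secreted phospholipase gene Pla2g1b (at least 19.4-fold), Rex2 (at least 5.95-fold), Triml1 (at least 8.50-fold), the epithelial transcription factor gene Elf3 (at least 11.5-fold) and the heparan sulphate proteoglycan gene Gpc3 (at least 15.7-fold). Zscan4e, Zscan4b, Zfp981, Zfp640 and Rex2 belong to families of near-identical copies that one probe set can read together, so which copy rose is uncertain. The other genes that fell most were U90926 (at least 8.98-fold), the chloride channel gene Ano1 (at least 30.1-fold), Aldh3a1 (at least 20.9-fold), Sbspon (at least 4.26 on the log2 scale), the endothelin gene Edn1 (at least 15.9-fold), Shisa3 (at least 9.99-fold), Akr1c14 (at least 5.37-fold), Mmp28 (at least 17.7-fold), Pllp (at least 16.1-fold) and the matrix proteoglycan gene Fmod (18.7-fold).

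**Figure D2:**
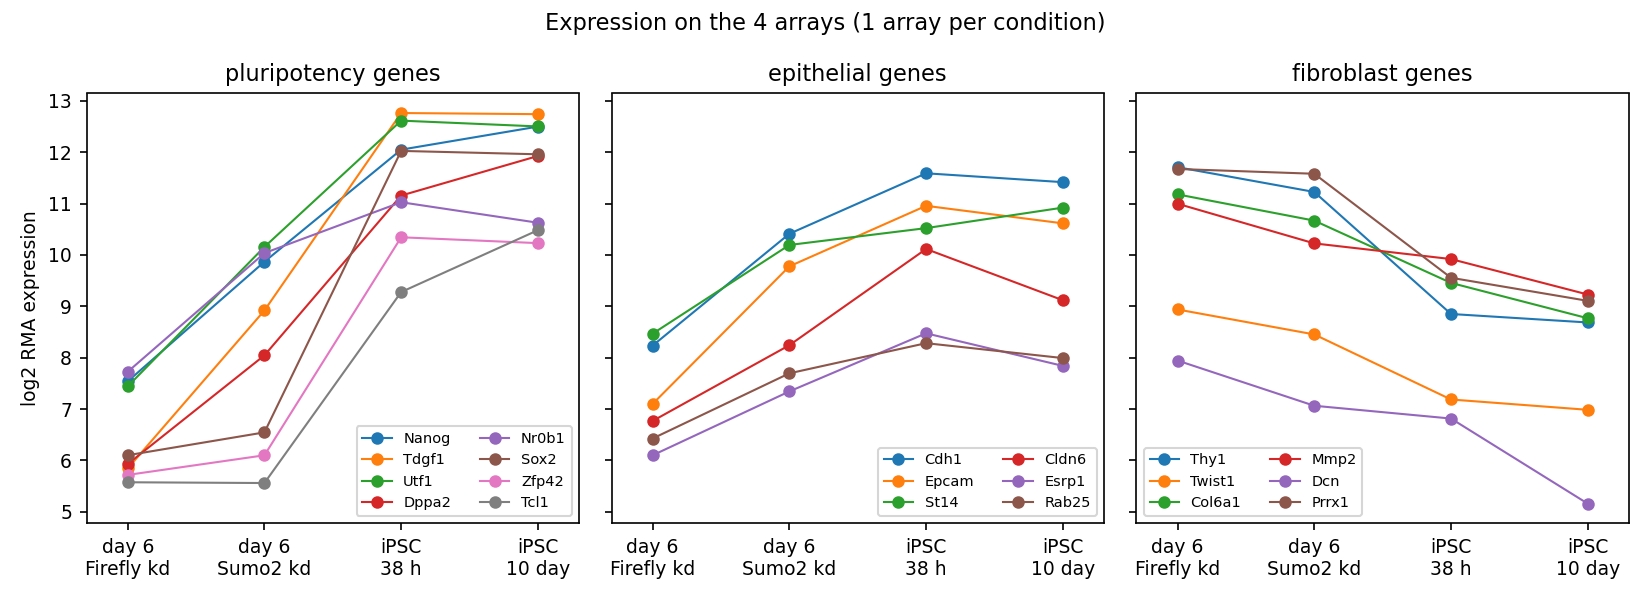
Log2 RMA expression (y axis) of genes from the pluripotency list with Sox2, the epithelial list and the fibroblast list on the 4 arrays (x axis); each point is 1 array and lines only join the points of a gene. Nanog read 7.54, 9.87, 12.05 and 12.50 from left to right, Sox2 6.10, 6.55, 12.03 and 11.96, and Thy1 11.71, 11.23, 8.85 and 8.69.

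In the lists, rose and fell stand for a limma adjusted p under 0.05 with no size rule. Of all 12735 measured genes, 7052 had an unadjusted limma p under 0.05, so a count of passing members alone does not set a list apart. Medians lay above their random intervals for the pluripotency, epithelial, cell cycle, 2-cell stage, trophoblast, chromatin and glycolysis lists. Those of the fibroblast, TGF-beta and p53 lists lay below. All other medians lay inside, such as that of the SUMO pathway (-0.23 to 0.51). Of the pluripotency list, 25 of 27 measured genes rose, 0 fell, and Nr0b1 (1.95) and L1td1 (0.33) did not pass (26 rose adjusted over the list alone; median log2 difference 2.66). Tdgf1, Dppa2 (floor 4.20), Zfp42 (floor 3.63), known as Rex1, and Tcl1 (floor 3.22) rose most as read, an order that rests on background, and Nanog rose by 3.57. Of 19 epithelial genes 10 rose and 0 fell (13 rose adjusted over the list alone; median 1.08), with the tight junction gene Cldn4 (2.67), Epcam (2.35), Cdh1 (2.18) and Cldn6 (2.11) first by size. Of 27 fibroblast and mesenchymal genes 14 fell, 3 rose and 10 did not pass (16 fell and 5 rose adjusted over the list alone; median -0.63). Thy1 (-2.70), the mesenchymal homeobox gene Prrx1 (-2.29) and the collagen genes Col6a1 (-1.81) and Col6a2 (-1.76) differed downwards most, while Postn (at least 4.01-fold), Pdgfra (at least 1.41-fold) and Lox (0.82) of the same list rose. TGF-beta target and contractile genes went both ways, with 6 of 15 down, 4 up and 5 not passing (7 and 4 adjusted over the list alone; median -0.28); Tgfb1i1 (-2.29) and Smad7 (1.73), an inhibitor of the pathway, lay at the ends.

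Of 16 glycolysis and hypoxia genes 15 rose, all but Gapdh (0.16) (16 of 16 adjusted over the list alone; median 1.37), with the angiogenic factor gene Vegfa (3.37), the phosphofructokinase gene Pfkp (3.16) and the mitophagy gene Bnip3 (3.01) first. Of 23 cell cycle genes 18 rose and 0 fell (22 rose adjusted over the list alone; median 0.99), led by the replication licensing gene Cdc6 (2.08). Of 16 DNA methylation and chromatin genes 13 rose and Tet3 fell by 1.51 (13 and 1 adjusted over the list alone; median 1.16), with Dnmt3l (floor 3.43) and Tet1 (3.70) ahead of Dnmt3b (2.17). Of 15 p53 and senescence genes 11 fell and Mdm2 (0.52) and Pmaip1 (0.88) rose (11 and 2 adjusted over the list alone; median -0.78). Those that fell most were Igfbp3 (-3.58), Phlda3 (-1.37) and the cell cycle inhibitor genes Cdkn2a (-1.27) and Cdkn2b (-1.20). Of 8 measured genes of the 2-cell stage 7 rose, all but Eif1a (0.23) (7 adjusted over the list alone; median 2.69), with Zscan4c (floor 3.13), Tdpoz3 (floor 1.17) and Zscan4d (floor 2.46) among the largest as read; these too are members of families of similar copies.

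Among the reprogramming factors Sox2 and Pou5f1 rose, the latter from 7.56 and 7.58 at day 6 to 8.56 and 8.39 in the 38 h and 10 day lines, and Klf4 and Myc fell, Klf4 to 10.82 and 11.09 and Myc to 8.80 and 8.06. Of 16 SUMO pathway genes 9 rose, 2 fell and 5 did not pass (10 and 2 adjusted over the list alone, 6 and 2 after cyclic loess; median 0.48), with the SUMO ligase gene Pias2 (1.49) and the SUMO protease gene Senp2 (1.24) up and Senp7 (floor -0.61) and Senp5 (-0.73) down. Of 9 trophoblast genes Ascl2 (floor 1.87), Eomes (floor 1.69) and Peg10 (0.93) rose and 0 fell (median 0.93). Of 9 primed pluripotency genes Otx2 (floor 2.57), Lefty2 (floor 1.52), Dnmt3b, Zic2 (1.87) and Foxd3 (0.70) rose and Sall2 (floor -0.59) fell (median 0.70). Of 11 germ layer genes Eomes, Sox1 (floor 0.60) and Gata6 (floor 1.11) rose and Nes (-1.26) and Foxa2 (-0.53) fell (median 0.40). Of 12 imprinted genes outside the Dlk1-Dio3 cluster Phlda2 (floor 2.07) rose, and Nnat (-1.52), Grb10 (-1.37) and the growth factor gene Igf2 (-1.25) fell (median 0.04). Of 13 genes on the list of those reported to hinder reprogramming, Chaf1b (1.42), Chaf1a (1.05), Trim28 (0.96), Kdm6a (0.87, a role not checked here) and Setdb1 (0.60) rose and Cdkn2a and Nr2c1 (-1.08) fell (median 0.36). Each of these counts was equal when adjusted over the list alone. After cyclic loess, 3 genes on the list of those reported to hinder reprogramming rose and 2 fell, with a median of 0.14. Of 4 genes of the Dlk1-Dio3 cluster (median -0.44) Meg3 passed limma downwards, with 6.15 and 5.87 in the 38 h and 10 day lines. Its day 6 values lay at the floor, so this rests on background, and 0 genes passed adjusted over the list alone.

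Markers of other cell types went both ways. Of 7 blood and macrophage markers Lyz2 (floor 0.95), Cd68 (1.04) and Fcer1g (floor 0.37) rose and Itgam (floor -0.15) fell (median 0.09). Of 7 neural and glial markers Olig2 (floor 2.33), Tubb3 (floor 2.59) and Stmn2 (0.41) rose and Mbp (floor -2.06) and Neurog2 (-0.62) fell (median -0.41). Of 5 endothelial markers Vwf (floor 0.58) and Egfl7 (0.67) rose and Tek (-2.44) fell (median 0.67; 2 and 2 adjusted over the list alone), of 7 muscle markers Des (1.69) rose and Acta1 (-1.05) and Myod1 (floor -0.48) fell (median -0.49; 1 and 3 adjusted over the list alone), and of 3 keratinocyte genes Krt17 (floor 2.04) rose (median 0.55). Of 18 stress genes 7 rose, led by Chac1 (floor 1.65) and Asns (1.80), and Egr1 (-1.09) and Jun (-0.74) fell (median 0.31). Of 12 widely expressed genes Tfrc (2.83), Hprt (1.28), Tbp (0.92), Pgk1 (0.89) and Sdha (0.71) rose and B2m (-1.37) and Rplp0 (-0.38) fell (median 0.03). Of 7 interferon response genes Stat2 (1.31) rose and Irf7 (floor -0.12) fell (median -0.08; 1 and 0 adjusted over the list alone). Of 7 sex chromosome genes Xist (floor 1.96) and Rhox5 (at least 3.54-fold) rose and the Y-linked genes Kdm5d, Uty and Eif2s3y fell (median 0.56). Where no count over the list alone is given here, it equalled the first. The mean had the sign opposite to the median for the neural and glial (0.38), endothelial (-0.18), interferon (0.06) and sex chromosome (-0.43) lists, so these give no direction. Kdm5d, Uty and Eif2s3y read 8.12, 8.13 and 7.71 in the control and 4.83, 5.29 and 5.30 in the 38 h line, with 4.55, 5.05 and 5.40 in the 10 day line. Xist read 8.29 and 8.99 in the 38 h and 10 day lines. The labels give the sex as a pool of male and female, so the lines and the day 6 cultures may differ in sex make-up. For the sex chromosome genes, an effect of reprogramming cannot be told apart from such a difference.

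The median difference over all measured genes was 0.15, and cyclic loess moved it to 0.02, so list medians here stand against a general shift of that size. Both arrays of a pair differ by condition, and the 3 ways to split the 4 arrays in pairs are too few for a test of the grouping.

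The third comparison asked whether the genes that set the iPSC lines apart already differed between the day 6 cultures. Genes high in iPSC tended to be higher in the culture labelled Sumo2 knockdown, and genes low in iPSC tended to be lower. Both lines were derived after Sumo2 knockdown, per the labels, and no line from a Firefly culture was measured. A lasting response to the knockdown, shared with the lines, therefore cannot be told apart from a step towards iPSC. Of 412 genes at least 4-fold higher in iPSC, 288 (69.9%) were higher in that culture, with a median log2 difference of 0.25 (quartiles -0.06 and 0.55) against a random interval of 0.01 to 0.08. Of 321 genes at least 4-fold lower in iPSC, 58 (18.1%) were higher, with a median of -0.31 (quartiles -0.53 and -0.08) against a random interval of -0.002 to 0.062. The remaining 12002 genes had a median of 0.03. Single pluripotency genes differed in this. Tdgf1, Nanog and Utf1 were at least 4-fold above the control and Dppa2 2.64-fold counted from the floor, whereas Sox2 differed by 0.45, Zfp42 by 0.38 and Tcl1 by -0.02, and these last lay below the measuring floor in both day 6 cultures; all 7 rose in iPSC.

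**Figure D3:**
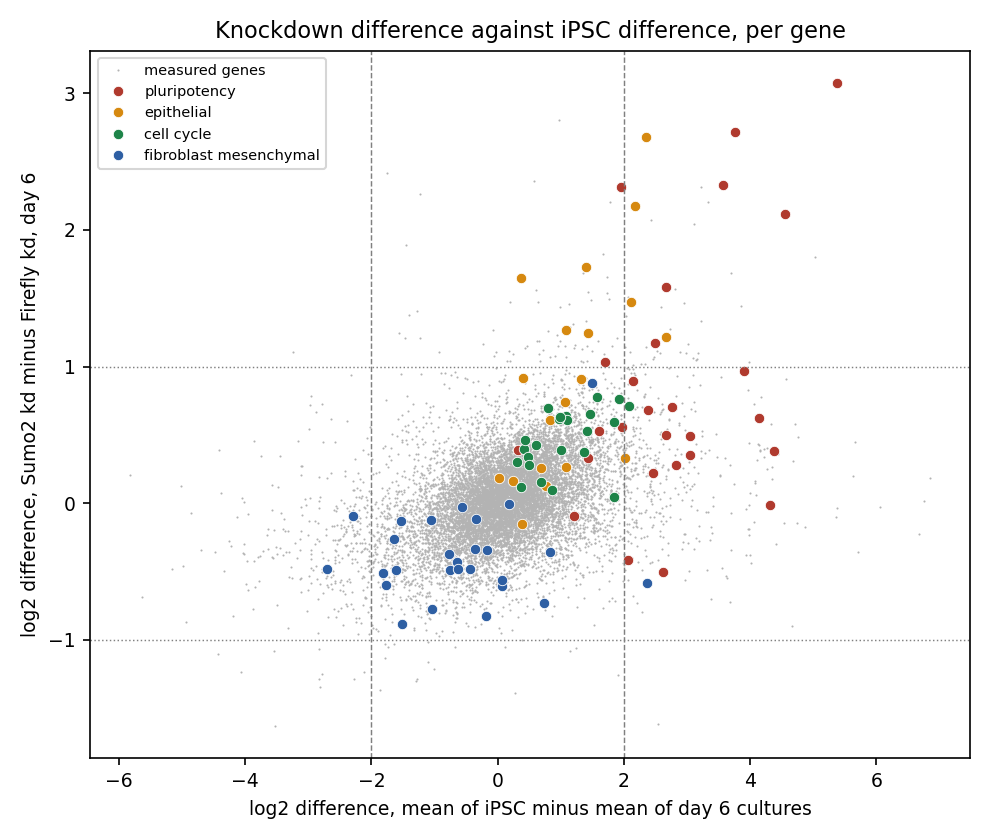
Each dot is a gene measured on at least 1 of the 4 arrays, with the log2 difference between the mean of the iPSC lines and the mean of the day 6 cultures on the x axis and that between the day 6 culture labelled Sumo2 knockdown and the Firefly control on the y axis; dotted lines mark 2-fold and dashed lines 4-fold. The pluripotency gene Tdgf1 lies at the upper right with 5.37 and 3.08, and most fibroblast genes lie below 0 on the y axis.

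Seen from the other side, 73 of the 111 genes at least 2-fold higher in the culture labelled Sumo2 knockdown were at least 2-fold higher in iPSC as well, 9 were lower and 29 lay within 2-fold. Of the 27 genes at least 2-fold lower, 20 were lower in iPSC, 4 higher and 3 within 2-fold.

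The fourth comparison set the iPSC lines against each other. X-linked genes as a set were higher in the 10 day line, and Cubn and Pou2f3 had the largest differences in favour of the 38 h line. Cubn, which encodes the receptor cubilin, was at least 7.80-fold higher in the 38 h line counted from the floor (log2 9.63 against 5.13), its partner Lrp2, which encodes megalin, at least 3.60-fold. The tuft cell transcription factor gene Pou2f3 was at least 6.15-fold higher there. Xlr3c was at least 2.57-fold higher in the 10 day line, Nxf3 at least 2.16-fold, Pnma5 at least 3.85-fold, Usp26 6.82-fold and Rhox1 at least 5.93-fold; all 5 lie on the X chromosome in assembly GRCm38.p6. Of 11754 measured genes, 121 were at least 2-fold higher in the 38 h line and 258 in the 10 day line, and 77 of the 258 were X-linked. The X-linked genes as a set had a median of 0.57 in favour of the 10 day line (n = 393 genes, random interval -0.05 to 0.02), against -0.03 for 11299 autosomal genes.

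**Figure D4:**
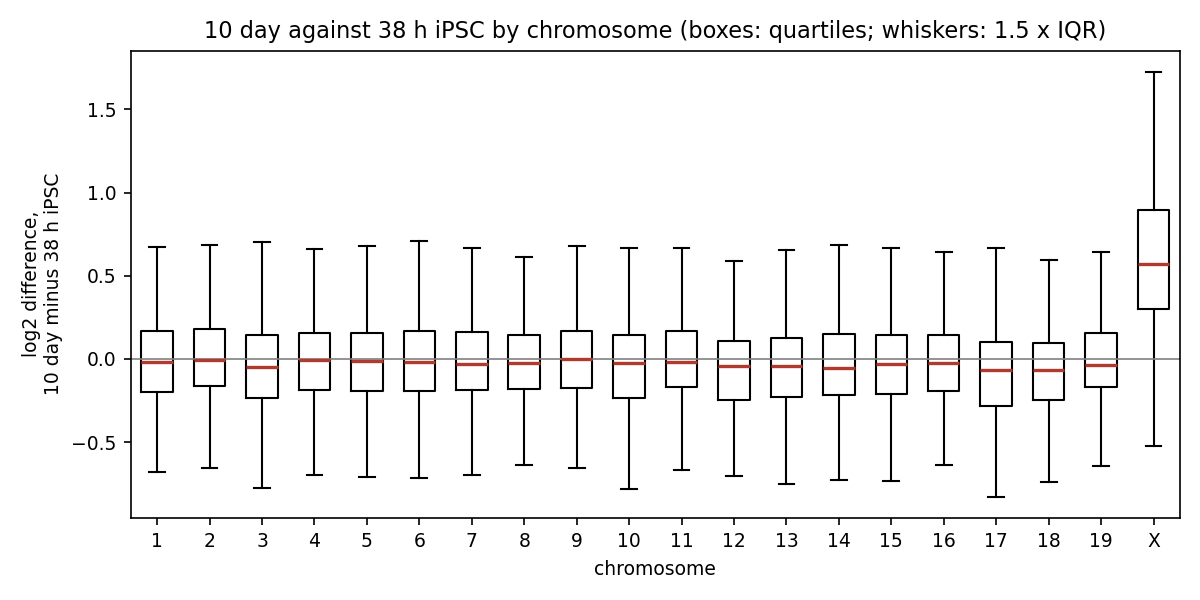
Log2 difference between the 10 day and 38 h iPSC lines (y axis) of measured genes on each chromosome of assembly GRCm38.p6 (x axis); red lines are medians, boxes the quartiles and whiskers the range within 1.5 interquartile ranges of the box. The X chromosome has a median of 0.57, and the medians of the autosomes lie between -0.069 and -0.002.

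The other genes with the largest differences were Map7d3 (at least 3.02-fold), Gna14 (at least 2.71-fold), the histone gene H4c17 (at least 1.96-fold), the imprinted gene Phlda2 (4.35-fold), Crmp1 (4.05-fold), Apela (4.02-fold), which encodes a peptide ligand of the apelin receptor, and Emb (3.88-fold) in favour of the 38 h line. In favour of the 10 day line they were the autophagy receptor gene Calcoco2 (8.23-fold), Tdpoz3 (at least 5.06-fold), the cartilage matrix gene Matn1 (at least 3.64-fold), the aquaporin gene Aqp3 (6.06-fold) and Slc16a5 (5.95-fold). For Emb and Slc16a5 the median over probe sets gave smaller log2 differences of 1.02 and -1.64 for 38 h minus 10 day. Of the 10 genes named on each side, 6 and 6 lay below the measuring floor in the line where they were lower, so their folds are counted from the floor. Their ranks as read rest on background.

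Whether the pluripotency list differed between the lines depended on how probe sets of a gene were joined. Its 27 genes had a median of -0.04 for 38 h minus 10 day, inside the random interval of -0.09 to 0.10, but of -0.18 with the median over a gene's probe sets, outside an interval of -0.09 to 0.10 drawn with those values. Of its members, Lin28a (1.03) was at least 2-fold higher in the 38 h line, and Tcl1 (-1.20) and Prdm14 (-1.41) in the 10 day line. Reprogramming factors (4 genes, median 0.11), cell cycle genes (23, 0.06), SUMO pathway genes (15, 0.05), DNA methylation and chromatin genes (16, 0.05), glycolysis genes (16, -0.04), stress genes (18, 0.02), widely expressed genes (12, 0.01) and genes reported to hinder reprogramming (13, 0.10) had medians inside their random intervals. Of 8 primed pluripotency genes (median -0.07) 3 were at least 2-fold higher in the 10 day line, Otx2 (-1.98), Lefty2 (-1.53) and Zic2 (-1.02).

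Fibroblast and mesenchymal genes were slightly higher in the 38 h line, in 19 of 25 cases (median 0.20, random interval -0.10 to 0.12), 0 of them 2-fold counted from the floor, and so were TGF-beta target and contractile genes in 14 of 15 (median 0.26, random interval -0.13 to 0.17). The epithelial list gave no clear direction: 11 of 19 genes were higher in the 38 h line and the median of 0.17 lay above the random interval of -0.14 to 0.15. With the median over a gene's probe sets the list median was 0.27, above an interval of -0.14 to 0.16 drawn with those values. But with the deposited values the mean was -0.05 and 0 genes were 2-fold higher in the 38 h line, while Dsp (-1.06) and Krt8 (-1.01) were 2-fold higher in the 10 day line. Higher in the 10 day line were the lists of 9 trophoblast genes (median -0.36), with Tfap2c (-1.42), Hand1 (floor -1.11) and Gata2 (-1.16), of 8 genes of the 2-cell stage (median -0.41), with Tdpoz3 and Usp17la (floor -0.92), and of 15 p53 and senescence genes (median -0.21), with Sesn1 (-0.76) and Perp (-0.72). The 4 sex chromosome genes measured were all X-linked and higher in the 10 day line (median -1.53), with Rhox6 at floor -2.06 and Rhox5 at -2.12 for 38 h minus 10 day.

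Of the Dlk1-Dio3 cluster, which is silenced in some iPSC lines, 3 genes were measured in the lines and all were higher in the 38 h line (median 0.51), Rian by 1.45. Begain (floor 0.41) and Dlk1 (0.26) differed by less, and Meg3 lay below the floor in both lines. The values therefore show a clear difference for Rian only, not for the cluster as a whole. The 12 other imprinted genes had a median of -0.06, with Phlda2 (2.12) and Plagl1 (-1.41) at the ends. Medians inside the random intervals were also found for 11 germ layer genes (0.20, with Gata6 at 1.30 and Sox1 at 1.03), 5 interferon response genes (-0.01), 5 blood and macrophage (-0.04), 4 endothelial (-0.21), 6 neural and glial (-0.05), 5 muscle (0.25) and 3 keratinocyte genes (0.06). These values compare 1 array with 1, and the labels do not separate the effect of the time from that of the clone.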

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

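Probe sets without a single gene name were counted only after the named genes had been seen. Of 5314 such probe sets measured at day 6, 92 were at least 2-fold higher in the culture labelled Sumo2 knockdown than in the Firefly control, which drew attention as signal outside the named genes, and 92 were at least 2-fold lower. Of 6655 measured on at least 1 of the 4 arrays, 1537 were at least 2-fold higher in the mean of the iPSC lines than in the mean of the day 6 cultures, and 427 lower.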

How the results depend on the processing

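All alternatives here were planned; the other splits of the arrays, folds counted from the measuring floor and random intervals drawn with scaled values came after the result was seen. No count split, named difference or list median outside its random interval changed direction under the alternatives run, while 9 of 77 list medians, all close to 0, changed sign, such as that of the widely expressed genes at day 6 (-0.09 with loess). Against intervals drawn with the same values, the TGF-beta median in iPSC against day 6 moved inside with loess or the median over probe sets. Just outside moved the interferon median at day 6 with loess, and outside with the median over probe sets the SUMO pathway median in iPSC against day 6 and the pluripotency median between the iPSC lines. The 138 genes 2-fold apart between the day 6 cultures became 76 with a filter at the 75th percentile (fewer genes tested), 810 with a 1.5-fold rule (59.3% higher in place of 80.4%), and 0 at adjusted p under 0.05 in limma with the spread of the iPSC pair (722 of 11740 at an unadjusted p under 0.05), a fit that takes the day 6 arrays to vary like the iPSC pair. The 379 genes between the iPSC lines became 178 and 1240 with the first 2 of these. Centring, loess, no filter and the median over probe sets kept both counts within 1.5 times. The iPSC count of 2981 (61.1% up, 51.7% with loess) ranged from 2064 with the 75th percentile filter to 3181, and from 2280 (without the Firefly array) to 3181 when single arrays were left out, where the lone array is assumed to vary like the remaining pair. The median day 6 difference of genes high in iPSC, 0.254, was 0.226 centred, 0.201 with loess, 0.298 with the 75th percentile filter, 0.222 for genes 2-fold apart and 0.226 to 0.266 when single iPSC arrays were left out. That of genes low in iPSC, -0.311, was -0.333 centred, -0.36 with loess, -0.332 with the median over probe sets and -0.244 for genes 2-fold apart. Apart from the filter, the cause was not tested. All 74 named differences stayed at least 2-fold under centring, loess and the median over probe sets, though not all counted from the measuring floor. Of the other splits of the 4 arrays, both gave 0 genes in limma (15 and 13 at an unadjusted p under 0.05, against 7052 for the real split). Each of them puts a day 6 and an iPSC array in the same group, so the large difference between cell types enters the spread. Their low counts were thus fixed by the design and lend the grouping no support, and 3 splits are too few to test it. No paired analysis was possible because the labels give no replicate numbers. Genes below the measuring floor, such as Sox2 at day 6, are limited by signal over background.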

Other observations

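Of the tests in this part, those on the Sumo2 probe set, on admixture, on array scaling of the pluripotency list and on the X-linked genes 4-fold apart as a matter of dosage were chosen only after the result was seen.

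A small group of genes was higher in the culture labelled Sumo2 knockdown than on all 3 other arrays. Of the 111 genes at least 2-fold above the control, 17 were above both iPSC lines as well, 15 of them with a gene name that the naming rule allows. Prob1 read 7.15 in the control, 9.57 in that culture and 6.51 and 6.68 in the 38 h and 10 day lines. Ly6g6c (10.32 against 8.06 in the control and 8.38 in the higher iPSC line), Cyyr1 (10.31 against 8.42 and 7.98), the complement regulator gene Cd59a (10.13 against 8.75 and 8.38), the semaphorin receptor gene Nrp2 (10.11 against 9.01 and 8.86) and the lipoxygenase gene Alox15 (9.43 against 8.32 and 5.84) were likewise highest in that culture, while the order of the control and the iPSC lines varied. These genes were chosen after their values were seen, and each value is 1 array.

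Extraembryonic endoderm genes were compared between the iPSC lines with a list written after Cubn, Lrp2 and Dab2 had been seen among the differences. Of 17 measured genes 5 were at least 2-fold higher in the 38 h line and 0 in the 10 day line, with a median of 0.26. Besides Cubn, Lrp2 and Dab2 (3.12-fold) these were the endoderm transcription factor gene Gata6 (2.46-fold, 8.42 against 7.12) and the laminin gene Lama1 (2.15-fold, 10.12 against 9.01). Without these 3 and the 6 measured members that also stand in the germ layer list, whose differences had been seen too, the other 8 genes had a median of 0.06 (percentile 65.0 among random lists), so the list gives no support beyond genes already seen. Gata4 (7.82 against 6.89) and Sox7 (7.17 against 6.20) were higher as well, while Hnf4a (6.67 against 6.93) and Col4a1 (8.13 against 8.51) were lower.

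Sumo2 transcript was nearly equal in the day 6 cultures, at a difference of -0.093. A saturated or unresponsive probe set is argued against by its range of 0.839 over the 4 arrays and its higher values in iPSC. Probe sets shared with Sumo2-like copies, not all of them separate readings, had a median difference of -0.258, so the share of signal from such copies in the main probe set stays open. Whether the day 6 arrays were exchanged stays open too, since a difference of -0.093 is small beside the spread of single genes between arrays. A knockdown that had faded by day 6 or acted in part of the cells was not tested.

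Pluripotency and epithelial genes were higher in the culture labelled Sumo2 knockdown. Cells with the full iPSC profile mixed in at 1 common share are argued against, because the share needed by 58 genes at least 16-fold higher in iPSC than in the control ran from -0.392% at the 10th percentile to 8.09% at the 90th: Nanog needed 15.5% and Utf1 16.5%, Zfp42 1.33% and Sox2 0.62%. A negative 10th percentile can arise from noise alone at a small share, and Zfp42 and Sox2 lay below the floor in both day 6 cultures. The argument against a common share therefore rests on the distance of the upper values from the median of 1.3%. A scaling trend over intensity is argued against as the whole cause by the pluripotency median of 0.773 after loess. Loess could hardly have removed a shift of a short list that is no such trend, so other array faults were not tested. Less fibroblast material in the culture stays open, since genes low in iPSC differed by amounts with an interquartile range of 0.451, too wide for 1 common dilution to be read or excluded. A biological effect of the knockdown was not tested, and with a Sumo2 difference of -0.093 the transcript does not show the knockdown.

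X-linked genes were higher as a set in the 10 day line than in the 38 h line, by 0.598 on the log2 scale relative to autosomes. Array scaling is argued against by the medians of the single autosomes, which lay between -0.069 and -0.002 while the X stood at 0.57. All 77 X-linked genes 2-fold higher stayed so after loess. That adds little, since loess fits a trend over intensity and could hardly have removed a shift of 1 chromosome. Set against the day 6 mean, the X stood at -0.091 relative to autosomes in the 38 h line and at 0.503 in the 10 day line. The values thus show no large loss of X-linked transcripts in the 38 h line below the day 6 level. But its X-linked differences had quartiles of -0.54 and 0.67 and include those between cell types, so a smaller loss cannot be excluded. A candidate explanation that the difference of 0.598 between the lines allows is 1 more active X chromosome in the 10 day line, as a hypothesis left open. Y-linked genes were low in both lines, and no karyotype was analysed here. Xist, which silences an X chromosome, was higher in the 10 day line (8.99 against 8.29), which speaks against the hypothesis in part. But Xist read near the floor in the day 6 cultures (6.22 and 6.72), though the labels give a pool of male and female. How well its probe set reports Xist was not tested. Dosage alone is argued against as the whole difference for the 11 of 393 X-linked genes that were at least 4-fold higher counted from the measuring floor (19 as read), among them Rhox1, Rhox5, Rhox6 and Usp26, against 9 of 11299 autosomal genes (19 as read). Germline genes that depend on DNA methylation could be higher in general, but 10 measured autosomal ones, from a list written after the X-linked genes had been seen, had a median of 0.153 (random interval -0.22 to 0.19), and although that lies inside the interval stated in advance as excluding it, 10 genes with Sohlh2 (2.13-fold) and Hormad1 (at least 1.96-fold) up and others down are too few to decide.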
